A study of Caenorhabditis elegans with 2 samples.

How the data were processed

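Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole first-stage (L1) larvae of Caenorhabditis elegans that carried an integrated transgene for the nuclear hormone receptor NHR-12 with a C-terminal GFP-FLAG tag. The series held 1 group of 2 biological replicates, per the labels. No second condition was present, so no comparison between groups was made. The authors used 1 control file in peak calling, per the deposited description of file derivations, and its reads were not analysed here.

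For each of the genome builds ce11 and ce10 the authors deposited 4 region lists: 1 for each replicate, 1 joint list called on the alignments of both replicates together, and the set of joint regions that passed their threshold on the irreproducible discovery rate (IDR), which compares the ranks of regions between replicates. The replicate and joint lists were the input to that step and held both peaks and background regions, per the deposited description of file types. A place in the IDR set did not require a region in the list of each replicate. In both builds the set was exactly the joint regions of highest signal. Membership therefore does not by itself show that the ranks of a peak agreed between replicates. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here. Each region carried a signal value, a score set by the authors' peak caller, with no stated scale. It was used to rank and describe regions within 1 list, and not as a level to compare between lists, apart from a remark on the mitochondrial peaks. Each region also carried a −log10 q-value from the authors' caller. All 164 IDR peaks tied at the top value of that column in the joint list, so it was not used for ranking. The p-value column was filled with a placeholder.

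Read counts were not part of the lists, so the sequencing depth of each replicate was unknown. Intervals on shares of peaks are exact (Clopper-Pearson) 95% binomial intervals and cover counting error only. The replicates differed in list length, with 26878 regions for replicate 1 and 30000 for replicate 2, and ranks were used only within a list.

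Coordinates are those of the ce11 lists, counted from 1. The lengths of the ce11 chromosomes were those of the reference assembly WBcel235, from which the sequence and the Ensembl release 115 annotation were taken. The ce10 lists were used only in their own coordinates, without annotation. Each region was represented by the point the authors' file gave, which lay at the middle of a region of fixed width in nearly all regions and is called the midpoint here. After the mitochondrial peaks had been seen, the comparisons with genes and sequence were restricted to nuclear peaks.

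A promoter window ran from 500 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Random placements drew the same number of midpoints uniformly within the same chromosomes (10000 draws, or 1000 for the match between replicates), and their one-sided p-value was the share of draws at least as large. The two-sided p-value for genomic features was 2 times the smaller tail. Matching within 100 bp was asked of the 164 strongest regions of each replicate. Correlations of log2 signal were tested with 100000 permutations. Chromosome shares were tested with the two-sided exact binomial test. Gene lists, sequence patterns and region sets were tested with the two-sided Fisher exact test. The 2080 distinct hexamers were 1 family. All families were adjusted by the Benjamini-Hochberg method.

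The 32 gene lists were fixed by gene symbol before the data were examined, as were the 19 sequence patterns, the tests, the windows and the rule for naming genes. That rule named nhr-12 and unc-119, the genes nearest to the 25 IDR peaks of highest signal with any gene holding the midpoint in its promoter window, up to 4 bound members of each list by highest signal, and the 10 hexamers of lowest p. The background of the gene list test was the 2683 protein-coding genes whose promoter window was touched by a region of each replicate's list. A list was tested where it had at least 5 members in that background, which left 23 lists. Sequence patterns were searched on both strands in windows of 201 bp centred on the midpoints. The background was windows of the same size centred 1100 bp away on both sides that did not touch an IDR peak.

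The gene list, hexamer and promoter tests were first tested on simulated data. With 10 ribosomal protein genes planted among 102 bound genes, the list was called in 20 of 20 runs, and in 0 of 20 runs with none planted. A hexamer planted in 20% of windows was called in 18 of 20 runs, with 4 other hexamers called over those runs, and no hexamer was called in 20 runs without one. In these hexamer runs the windows and their background were both flanks. They therefore do not cover calls that come from a difference in base composition between peaks and flanks. The promoter test found a planted excess of 30% in 20 of 20 runs and gave 0 calls in 20 runs on random positions.

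Alternatives fixed before the data were examined were the ce10 lists, the stronger part of the IDR peaks, other distances, windows and backgrounds, and each replicate's own 164 strongest regions in place of the joint call. Further alternatives were added after seeing the data: nuclear or autosomal peaks only, the weaker regions of the joint list as background, and peak windows shuffled with their dinucleotide counts kept (10 per window). Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.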

Results

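The binding of NHR-12, a member of the large nematode family of nuclear hormone receptors, was mapped by ChIP-seq in L1 larvae, the first larval stage after hatching. The animals were whole, of mixed sex, and came from a strain that stably expressed NHR-12 fused to GFP and FLAG. There were 2 biological replicates of this 1 group. The question posed by the design was where in the genome the tagged protein was found.

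The authors' IDR set held 164 peaks in ce11, most of them 376 bp wide, of which 146 lay on the 6 nuclear chromosomes and 18 on the mitochondrial genome. It was the top of the joint list of 3817 regions: the 164 joint regions of highest signal were the 164 IDR peaks. Signal values in the set ran from 37.1 to 739, with a median of 51.4. The nuclear peaks covered 54.7 kb, which is 0.0546% of the nuclear genome. The same authors' procedure in ce10 gave 198 peaks, 19 of them mitochondrial. Read depth was unknown, because the lists hold no counts.

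The 13 strongest IDR peaks were all mitochondrial. The strongest lay at 12308 to 12475 of the mitochondrial genome inside the gene MTCE.35, with a signal of 739, and the next at 4551 to 4926 inside MTCE.21, with a signal of 671. Replicate 1 listed a region within 100 bp of 16 of the 18 mitochondrial peaks, and replicate 2 of 0. No mitochondrial region was listed for replicate 2 in either build, against 21 for replicate 1 in each.

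The strongest nuclear peak, with a signal of 130, lay on chromosome III at 3867391 to 3867766, 275 bp upstream of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. A peak with a signal of 111 stood 42 bp upstream of rpr-1 (WBGene00045238), the RNA component of RNase P, in an intron of ints-8 on chromosome I (13463725 to 13464100). Another, with a signal of 97.8, lay on chromosome I at 13663208 to 13663583 over the 5′ end of ints-4 (WBGene00012234). Both ints genes encode subunits of Integrator, a complex that processes small nuclear RNA. Of the 12 nuclear peaks among the 25 strongest, 9 were on the X chromosome, and 8 of those 9 lay outside promoter windows.

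These X peaks included an intergenic peak at 13700688 to 13701063 with a signal of 124, 3088 bp from the 5′ end of the noncoding RNA gene K02D3.5. Intergenic peaks at 11094035 to 11094410, near the tRNA gene W02H3.t1, and at 9465650 to 9466025, near the noncoding RNA gene ZK899.10, had signals of 113 and 110. A peak at 2996848 to 2997223, nearest to the piRNA gene 21ur-12946, lay in an intron of Y41G9A.17 with a signal of 105. A peak in an intron of mom-1, a gene of Wnt ligand secretion, had a signal of 97.2 at 6296331 to 6296706. Intergenic peaks nearest to F20B6.9, nspc-17 and F22H10.2 had signals of 103.7, 91.4 and 89.1. The X peak in a promoter window was that of nipi-3 (15607532 to 15607907), which encodes a Tribbles-like kinase, with a signal of 97.

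**Figure D1:**
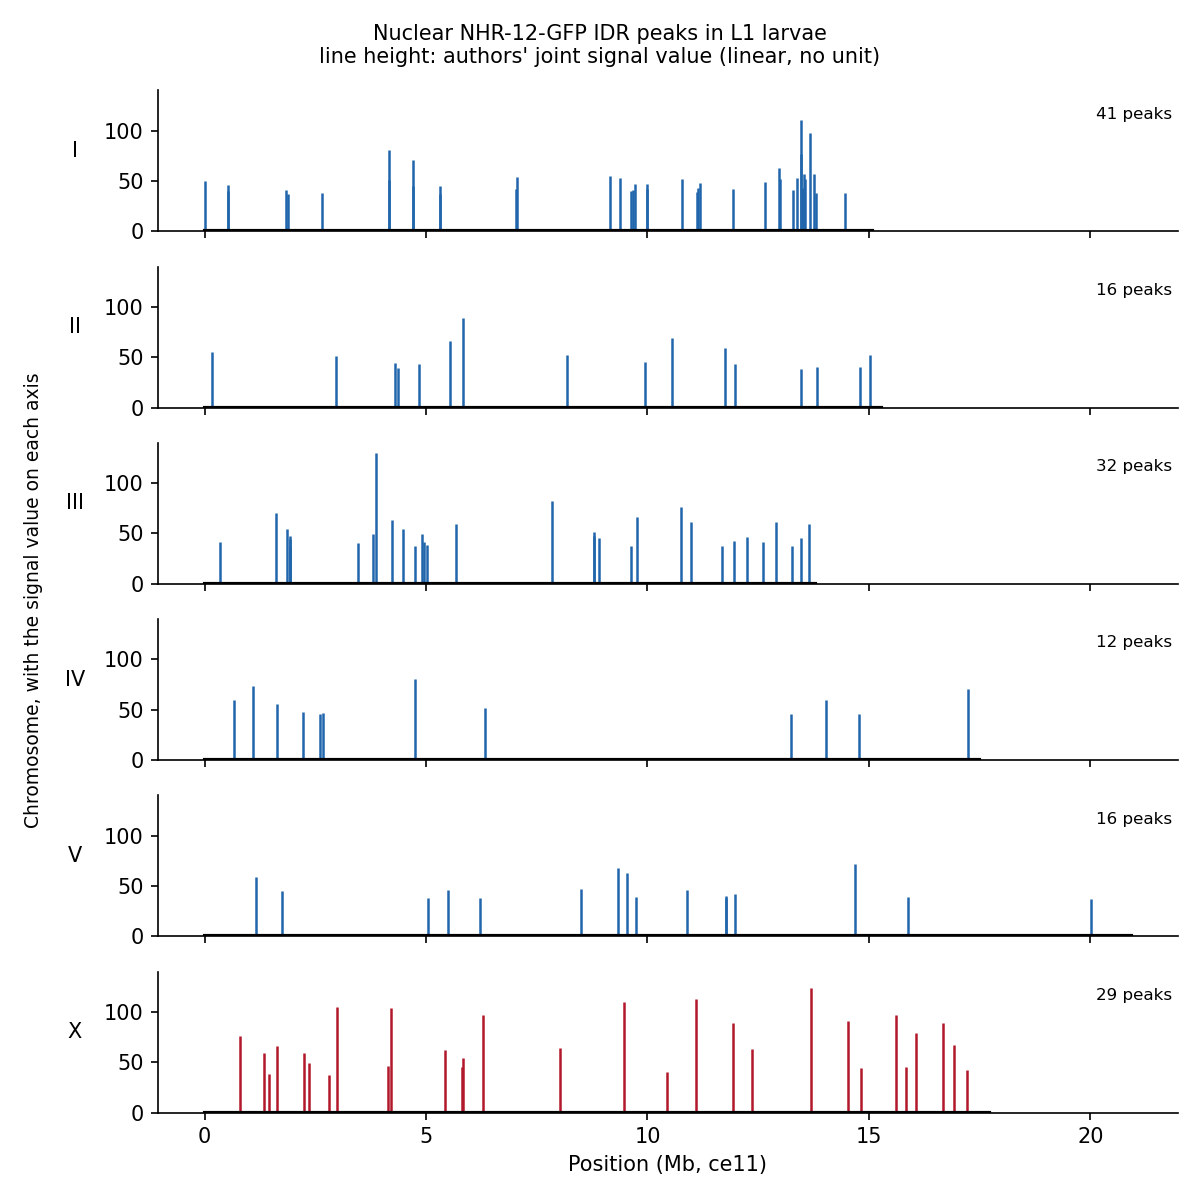
Position (Mb, ce11) of the 146 nuclear IDR peaks on each chromosome, with line height giving the authors' joint signal value on a linear scale without a unit (autosomes in blue, X in red). Chromosome I held 41 peaks and X held 29, and several of the tallest lines are on X.

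The nuclear peaks were listed in both replicates far more often than the mitochondrial ones. A region of replicate 1 lay within 100 bp of 141 of the 146 nuclear peaks, a region of replicate 2 within 100 bp of 145, and both replicates had one at 140. The median rank of these matched regions was 108 in replicate 1 and 80 in replicate 2. The weakest matched region ranked 22816 of 26878 in replicate 1 and 5970 of 30000 in replicate 2. These lists held background regions too, and covered 10.3% and 10.6% of the nuclear genome. The IDR peaks came from a joint call on both replicates, so a listing alone is weak evidence that a peak was reproduced. The rpl-3 peak ranked 19 in replicate 1 and 3 in replicate 2. At the mom-1 peak no region of replicate 1 had its midpoint within 100 bp, and the region of replicate 2 ranked 14. Whether a replicate 1 region with a more distant midpoint overlapped that peak was not checked.

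Of the 164 strongest regions of replicate 1, 68 (41.5%) had one of the 164 strongest of replicate 2 within 100 bp. Random placement of the n = 164 regions gave a mean of 0.0287% and at most 1.22% in 1000 draws (p = 0.001, the smallest they can give). With nuclear regions only, 62 of 146 (42.5%) matched. Across the 140 nuclear IDR peaks listed in both replicates, the log2 signals correlated with Pearson r = 0.335 (permutation p = 4e-05, adjusted p = 5.33e-05) and Spearman rho = 0.297 (permutation p = 0.00046, adjusted p = 0.00046). Without the 2 peaks farthest from the median of replicate 1, r was 0.365. Across all 3824 nuclear regions listed in both replicates, r was 0.413 and rho 0.183 (permutation p = 1e-05 for each, the smallest they can give, adjusted p = 2e-05). These correlations are across regions, which are not independent replicates, 4 were computed, and the IDR peaks had been selected on a signal made from both replicates. Below the strongest regions the lists shared little: 3824 of the 26857 nuclear regions of replicate 1 (14.2%) had a region of replicate 2 within 100 bp, where random placement gave 5.86%.

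**Figure D2:**
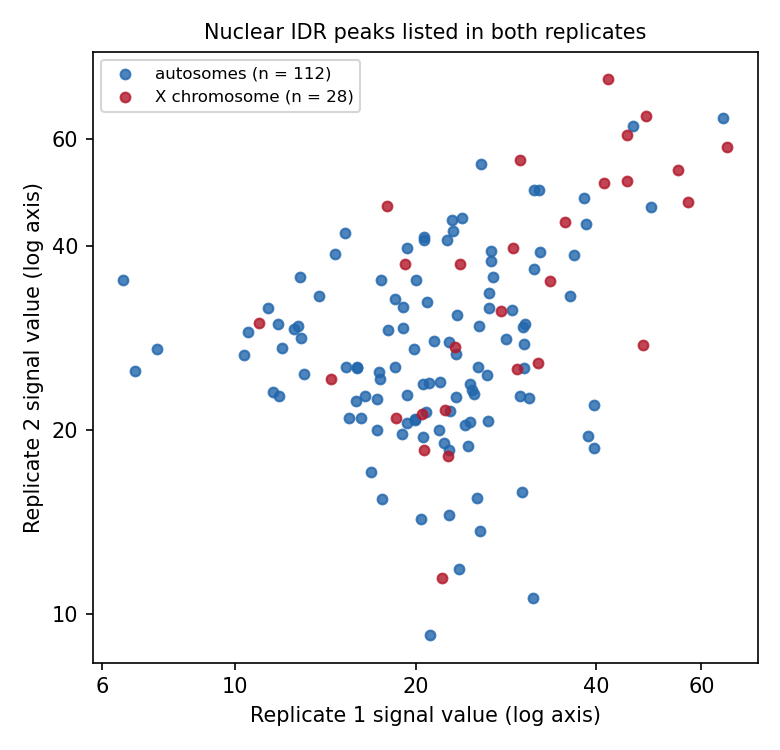
Signal value of replicate 1 against that of replicate 2 (both log axes, the authors' scores without a unit) for the 140 nuclear IDR peaks listed in both replicates, 1 point per peak, with X peaks in red. The Spearman correlation was 0.297.

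Chromosomes I and III held more peaks than their length gives, and chromosomes IV and V fewer. Chromosome I had 41 of 146 peaks (28.1%, 95% interval 21 to 36.1), 1.87 times its 15% of the nuclear genome (exact binomial test, Benjamini-Hochberg adjusted p = 0.000367 over 6 chromosomes). Chromosome III had 32 peaks (21.9%), 1.59 times its share (exact binomial adjusted p = 0.0114). Chromosomes IV and V had 12 (8.22%) and 16 (11.0%) peaks, 0.471 and 0.525 times their shares (exact binomial adjusted p = 0.0043 for each). Chromosome II with 16 peaks (exact binomial adjusted p = 0.201) and X with 29 peaks (19.9%, adjusted p = 0.514) did not pass the test. Peaks can lie in clusters, so p-values over peaks are smaller than independent sites would give. On the autosomes 71.8% of peaks lay in the outer parts of the chromosomes that make up 66.7% of their length (exact binomial p = 0.281), and with replicate 2 alone 76.1% did (exact binomial p = 0.0216).

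X stood apart among the strongest peaks. Of the 82 strongest IDR peaks 66 were nuclear, and 20 of those 66 (30.3%, 95% interval 19.6 to 42.9) were on X, against 17.7% by length (exact binomial adjusted p = 0.0422). In this stronger set the calls for chromosomes I, III and IV ended, with exact binomial adjusted p = 0.17 for chromosome I and 0.231 for the others. With replicate 1 alone the calls for chromosome III (exact binomial adjusted p = 0.105) and IV (0.339) ended, and with replicate 2 alone that for IV (0.0752). With expected shares from regions in both lists the calls for III and V ended (exact binomial adjusted p = 0.0564 for each).

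Peaks were concentrated just upstream of protein-coding genes. The midpoint of 79 of the nuclear peaks (n = 146, 54.1%, 95% interval 45.7 to 62.4) lay in a promoter window, 4.30 times the mean of 12.6% in random placements, whose highest value was 26.0% (p = 0.0001, the smallest they can give). The median distance to the nearest 5′ end of a protein-coding gene was 380 bp, against a median of 1690.5 bp in random placements (n = 146, p = 0.0001, the smallest they can give). The 3652 weaker nuclear regions of the joint list lay in promoter windows less often, with 772 of them (21.1%, Fisher exact odds ratio 4.40, 95% interval 3.10 to 6.25, p = 1.73e-17). Overlap with regions bound by many unrelated factors (high-occupancy regions) or with blacklisted regions was not tested, so the excess at promoters, and those at ribosomal protein and snRNA genes, are not shown to be specific to NHR-12. The promoter share was 47.6% for the strongest regions of replicate 2 alone and 45.1% for those of replicate 1 alone.

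Autosomal and X peaks differed in this. Of 117 autosomal peaks 72 (61.5%) were in promoter windows, and of 29 X peaks 7 (24.1%), a Fisher exact odds ratio of 4.97 (95% interval 1.86 to 14.9, p = 0.000352). Random placements on X gave a mean of 10.4% in promoter windows and at most 34.5% (n = 29, one-sided p = 0.0277, two-sided adjusted p = 0.129 over 7 feature classes). The median distance to a protein-coding 5′ end was 328 bp on autosomes and 1710 bp on X. This split was made after the strong X peaks had been seen.

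Each peak was given a single feature class, with promoter windows assigned first, so the excess there lowers the shares of the other classes by construction. The values below are shares of all peaks, and peaks outside promoter windows were not tested apart. A single peak (0.685%) had its midpoint in a coding exon, that of pks-1 on X at 5429322 to 5429697, where random placements gave 21.7% (n = 146, Benjamini-Hochberg adjusted p = 0.000467 over 7 feature classes), and introns held 23 peaks (15.8%) against 33.1% (adjusted p = 0.000467). No peak fell in a 3′ UTR, against 2.87% at random (n = 146, adjusted p = 0.0375), or in a 5′ UTR outside a promoter window, against 0.866% (adjusted p = 0.62). Noncoding RNA genes held 6 peaks (4.11%) against 1.30% (n = 146, adjusted p = 0.0375). Intergenic sequence held 37 peaks (25.3%), and the 27.5% at random did not differ past the threshold (n = 146, adjusted p = 0.62). On X, 17 peaks (n = 29, 58.6%) were intergenic, against 36.4% at random, which did not pass the threshold either (adjusted p = 0.129). The call for 3′ UTRs ended with the stronger peaks (n = 66, adjusted p = 0.403), with either replicate alone (0.409 and 0.227) and with autosomal peaks only (0.0856), and that for noncoding RNA genes ended with replicate 1 alone (adjusted p = 0.0515).

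**Figure D3:**
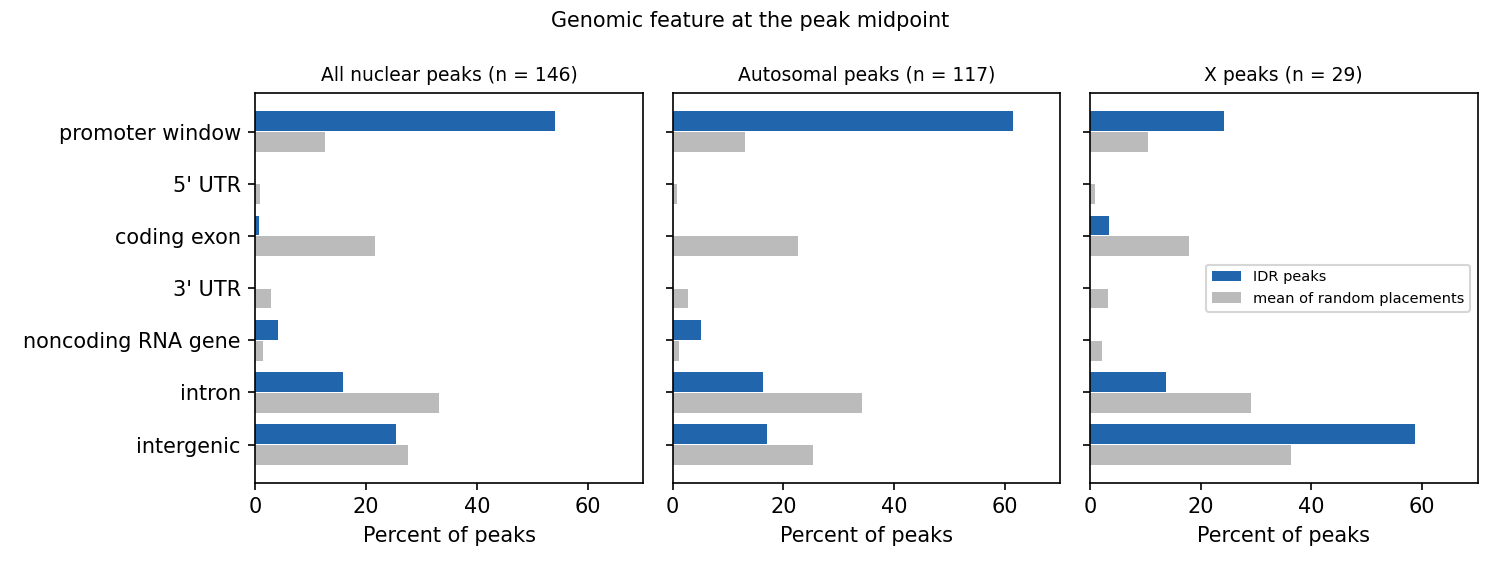
Percent of peaks in each class of genomic feature (blue) and the mean percent over 10000 random placements in the same chromosomes (grey), for all 146 nuclear peaks, the 117 autosomal peaks and the 29 X peaks. Promoter windows held 54.1% of all nuclear peaks, and intergenic sequence held 58.6% of X peaks.

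The promoter windows with a peak belonged to 102 protein-coding genes, and 23 peaks lay in the windows of at least 2 genes at once, so that the gene concerned is not known there. Of the 37 cytosolic ribosomal protein genes in the background, 10 had a peak (27%), against 92 of 2646 other genes (3.48%), an odds ratio of 10.3 (95% interval 4.30 to 22.7, Fisher exact test, Benjamini-Hochberg adjusted p = 1.38e-05 over 23 lists). The members of highest signal were rpl-3 (130), rpl-35 (82.2), rpl-20 (80.2) and rpl-15 (59.7). The peaks of rpl-20, rpl-15, rps-12, rpl-12 and rps-20, 5 of the 10, also lay in the promoter window of another gene (Y17G9B.5, K11H12.8, ska-3, lin-54 and ekl-4). With an upstream limit of 250 bp the call for this list ended (4 of 26 genes, odds ratio 5.54, Fisher exact adjusted p = 0.0876). The odds ratio was 4.73 with joint-list genes as background, 16.3 with replicate 2 alone, 17.3 with the stronger peaks and 31.6 against all protein-coding genes, past the threshold in each.

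Histone and chaperone genes passed the test on few members. Of 5 histone genes in the background 3 had a peak (odds ratio 38.8, 95% interval 4.40 to 470, Fisher exact adjusted p = 0.00581): his-37 (62.7) and the divergent pair his-67 and his-68, which share 1 peak (41.6). Among the strongest regions of replicate 2 alone, 1 of the 5 histone genes had one in its window (Fisher exact adjusted p = 0.558). Of 17 genes in the list of heat shock proteins and chaperones 4 had a peak (odds ratio 8.05, 95% interval 1.88 to 26.7, Fisher exact adjusted p = 0.0245). This list was fixed by symbol, so genes of this kind under other symbols were not counted. The 4 were cct-8 (73.8) and cct-1 (52.5), subunits of the cytosolic chaperonin, and dnj-19 (46.1) and dnj-9 (43.0), of the DnaJ family. Only the dnj-9 peak was in no other promoter window, and those of cct-8, cct-1 and dnj-19 lay nearer to the 5′ ends of Y55F3AR.2, mig-5 and nhr-47. The chaperone call ended with the stronger peaks (Fisher exact adjusted p = 0.322), with an upstream limit of 250 bp (0.976) and with joint-list genes as background (0.233), and the histone call ended with the stronger peaks (0.582). Across the alternatives the odds ratio ran from 2.24 (250 bp) to 19.7 (replicate 2 alone) for chaperones and from 6.64 (replicate 2 alone) to 50.3 (replicate 1 alone) for histones.

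The other 20 lists tested did not pass. Translation factors had 3 of 16 genes with a peak (eef-2, shared with clsp-1, eif-3.C and eif-3.B, odds ratio 5.98, Fisher exact adjusted p = 0.12), and they and the cell cycle list passed with replicate 1 alone (adjusted p = 0.0497 for each), as did translation factors against all protein-coding genes (0.0119). The mitochondrial respiratory chain had 2 of 19 (cox-5A and atp-1, the latter shared with mcrs-1, Fisher exact adjusted p = 0.53) and the cell cycle list 2 of 15 (cdc-48.1 and cdk-5, adjusted p = 0.418). These 2 members of the cell cycle list were placed there by symbol alone, and a role in the cell cycle was not checked. Among nuclear hormone receptors 2 of 39 genes had a peak, nhr-47 (the peak shared with dnj-19) and nhr-256 (odds ratio 1.37, 95% interval 0.158 to 5.46, Fisher exact adjusted p = 1). Chemoreceptors had 1 of 128, sri-5, whose peak also lay in the window of rsr-1 (odds ratio 0.191, 95% interval 0.00476 to 1.11, Fisher exact adjusted p = 0.417). No gene with a peak was found among the other 15 lists tested: homeobox, bHLH and bZIP factors, proteasome subunits, the vacuolar ATPase, collagens, cytochrome P450, UDP-glucuronosyltransferases, glutathione S-transferases, lipid metabolism, C-type lectins, neuropeptides and insulins, F-box and MATH-BATH genes, insulin and TGF-beta signalling, and neuron markers. With at most 23 background members each, these lists leave wide intervals, up to an odds ratio of 27.9 for the bHLH factors. Another 9 lists had fewer than 5 members in the background and were not tested: GATA factors, ABC transporters, Wnt and Notch signalling, heterochronic genes, and the markers of intestine, body muscle, hypodermis and seam, pharynx and germline. Of their members mig-5, a Dishevelled homologue in the Wnt list, had a peak, shared with cct-1.

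Small nuclear RNA genes had the largest excess among the noncoding RNA classes. The midpoints of 8 peaks lay within 200 bp of an annotated snRNA gene, where random placements gave a mean of 0.078 and at most 3 (n = 146, Benjamini-Hochberg adjusted p = 0.0006 over 6 classes). These were peaks at sls-2.1 (88.5), sls-2.4 (2 peaks, 80.8 and 51.0), sls-2.2 (65.9), sls-2.8 (47) and sls-2.9 (40.6), genes for the SL2 spliced leader RNA that is trans-spliced to downstream genes of operons, and at R07E5.16 (61.8) and T11F9.15 (41.7). The sls-2.1 peak lay on chromosome II at 5844735 to 5845110. Genes for snoRNA had 4 peaks against 0.279 at random (n = 146, adjusted p = 0.0021), and miRNA genes 2 against 0.173 (adjusted p = 0.028), at cel-mir-52 and cel-mir-2218a. Several of these peaks also lay in promoter windows of protein-coding genes: sls-2.8 (Y75B8A.23 and tim-1), T11F9.15 (snr-4), cel-mir-2218a (maea-1) and the snoRNA genes Y53F4B.47 (cmtr-1) and F55A11.10 (F55A11.11). The sls-2.9 peak also counted for the tRNA gene M01E5.t1. Genes for tRNA had 2 peaks against 0.425 (n = 146, adjusted p = 0.0987), rRNA genes 0 against 0.0294 and piRNA genes 1 against 2.50 (adjusted p = 1 for both). Against the weaker joint regions the snRNA excess had an odds ratio of 19.1 (95% interval 6.57 to 53.2, Fisher exact adjusted p = 1.25e-06), and the snoRNA and miRNA calls ended (adjusted p = 0.167 and 0.0706). In that comparison piRNA genes were near fewer peaks, 1 of 146 against 184 of 3652 (odds ratio 0.13, 95% interval 0.00325 to 0.745, Fisher exact adjusted p = 0.0288). The snoRNA and miRNA calls also ended with the stronger peaks (n = 66, random placements, adjusted p = 0.216 for each), and the miRNA call with replicate 1 alone (0.252). The excess over random was still 8.73-fold for snoRNA and 11.8-fold for miRNA with the stronger peaks, against 14.3 and 11.6 in the main result. Against the weaker joint regions the odds ratios were 2.31 and 8.43. The ended calls therefore do not show that the excess was absent.

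The peak windows were rich in GAGA and CG-containing sequence. The EOR-1-like pattern AGAGACGCAGA was in 13 of 146 windows (8.90%) and 1 of 290 flanking windows (0.345%), an odds ratio of 28.1 (95% interval 4.13 to 1204, Fisher exact test, Benjamini-Hochberg adjusted p = 8.66e-05 over 19 patterns). The GAGA box GAGAGAGA was in 13 windows (8.90%) against 0.690% of flanks (odds ratio 14, 95% interval 3.10 to 129.5, Fisher exact adjusted p = 0.000153), and the E2F pattern TTSSCGC in 34 (23.3%) against 7.93% (odds ratio 3.51, 95% interval 1.91 to 6.55, adjusted p = 0.000153). Across the alternatives with a finite value the odds ratio ran from 6.27 (weaker joint regions) to 142 (shuffled windows) for the EOR-1-like pattern, which rests on 1 flank with a match, and was 9.23 with replicate 2 alone and 8.93 against promoters without a peak. That of the GAGA box ran from 2.02 (stronger peaks) to 19 (50 bp each side), with 3.09 against weaker joint regions, 3.67 against promoters without a peak and 7.01 with replicate 1 alone, and that of the E2F pattern from 2.07 (shuffled windows) to 5.73 (replicate 1 alone). The nuclear receptor core site AGGTCA was in 10 windows (6.85%) against 3.45% (odds ratio 2.06, 95% interval 0.748 to 5.65, Fisher exact adjusted p = 0.274), and the variant AAGTCA in 9 (6.16%) against 9.31% (odds ratio 0.641, adjusted p = 0.484), so neither passed the test.

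Less frequent in peak windows than in flanks were TTTCAG, labelled initiator-like when the patterns were fixed (17.1% against 35.9%, odds ratio 0.37, Fisher exact adjusted p = 0.000179), the tRNA B box (3.42% against 11.4%, odds ratio 0.277, adjusted p = 0.0235), the HSF pattern (8.22% against 17.6%, odds ratio 0.42, adjusted p = 0.0287) and the GATA pattern (23.3% against 35.5%, odds ratio 0.552, adjusted p = 0.0319). Whether TTTCAG marks initiators here was not tested, and flanks were not matched to peaks for position relative to genes. Against promoters without a peak the odds ratio of TTTCAG was 0.522 (Fisher exact adjusted p = 0.00704). The windows had a median GC content of 44.3%, against 36.3% in the flanks. The calls for GATA, HSF and the B box ended with either replicate alone, where the odds ratio of the B box was 0.41 with replicate 2 and 0.854 with replicate 1. The HSF call ended under every alternative run, and the B box call under all but autosomal peaks only (Fisher exact adjusted p = 0.0246). That for GATA also ended with 50 bp and 200 bp each side (Fisher exact adjusted p = 0.384 and 0.526). It held against promoters without a peak, against weaker joint regions and with autosomal peaks only. Against peak windows shuffled with their dinucleotide counts kept, the odds ratios were 1.09 for TTTCAG, 0.886 for HSF, 0.842 for GATA and 0.357 for the B box (95% interval 0.112 to 0.876, Fisher exact adjusted p = 0.089). With the 66 stronger nuclear peaks no pattern passed (Fisher exact adjusted p = 0.0785 for the EOR-1-like and the E2F pattern). The remaining 10 of the 19 patterns did not pass, but under alternatives FOX was less frequent (odds ratio 0.151 against promoters without a peak, Fisher exact adjusted p = 0.00178, and 0.184 against weaker joint regions, adjusted p = 0.0121) and the SP1-like pattern more frequent (3.44 with replicate 1 alone, adjusted p = 0.0294).

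**Figure D4:**
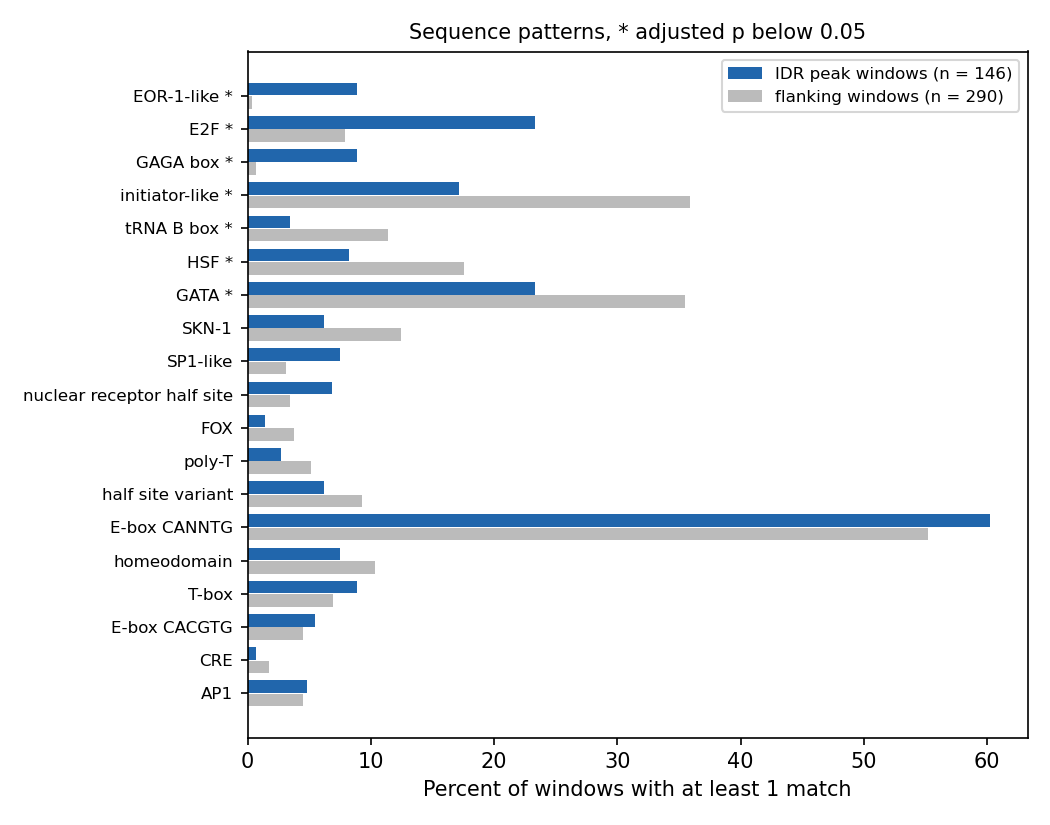
Percent of windows reaching 100 bp to each side of the midpoint with at least 1 match to each of the 19 sequence patterns, in 146 nuclear IDR peak windows (blue) and 290 flanking windows (grey), ordered by p. The EOR-1-like pattern was in 8.90% of peak windows and 0.345% of flanks.

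Of all distinct hexamers, 218 differed between peak windows and flanks (Fisher exact test, Benjamini-Hochberg adjusted p under 0.05), 159 of them more frequent in peaks and 59 less. GAGAGA led, in 63 of 146 windows (43.2%) against 11.4% of flanks (Fisher exact adjusted p = 4.24e-10). CGCGCA was in 26.0% against 2.76% and GACGCA in 26.7% against 3.10% (Fisher exact adjusted p = 4.61e-10 for both). The other hexamers among the 10 of lowest p were ACGCAG, CGTCTC, GCACGC, AGAGAC, AGACGC, AGAGAG and ACGCGC, all more frequent in peaks, with adjusted p from 4.61e-09 to 3.83e-07. Most of these are parts of patterns given above, but were in far more windows than the full patterns. GAGAGA was in 63 windows and ACGCAG in 40, and the GAGA box and the EOR-1-like pattern in 13 each. Most windows with these hexamers therefore lacked the full pattern. GACGCA, ACGCAG, CGTCTC (on the other strand), AGAGAC and AGACGC are parts of the EOR-1-like pattern, and GAGAGA and AGAGAG of the GAGA box. With autosomal peaks only, CGCGCA ranked 11 by p, in 22.2% of windows against 3.02% of flanks. Against shuffled windows 89 hexamers passed, of which 46 were among the 218.

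No IDR peak lay near the genes carried in the strain's genotype, but almost none was expected at random. Random positions gave a mean of 0.0376 IDR peaks within 25 kb for nhr-12 and 0.132 for unc-119. The absence of IDR peaks therefore cannot tell whether the transgene added signal. Within 25 kb of nhr-12 (WBGene00003611, chromosome V, 10082133 to 10084049, minus strand) there was no IDR peak and no region of the joint list. Replicate 1 listed 2 regions there and replicate 2 listed 4, against means of 12.4 and 14.2 at random positions of the chromosome (permutation of position, adjusted p = 1 for both, tested for an excess). Within 25 kb of unc-119 (WBGene00006843, chromosome III, 10902641 to 10908935), the gene whose mutation marks the parent strain, there was no IDR peak either. Replicate 1 listed 26 regions there against a mean of 15.9 (permutation of position, adjusted p = 0.163), replicate 2 listed 17 against 17.5, and the joint list 4 against 2.36 (adjusted p = 0.98). Within 50 kb of unc-119 replicate 1 listed 47 regions against a mean of 29.9 (permutation of position, unadjusted p = 0.0045), and replicate 2 listed 34 against 33.1.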

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

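The tests of the mitochondrial peaks were all chosen after the result was seen. The comparisons of the report used nuclear peaks, and a signal appeared in the data they left out: 18 IDR peaks and 21 regions of the replicate 1 list lay on the mitochondrial genome. All 13 IDR peaks with a signal above that of the strongest nuclear peak were among them, and 18 of the 20 strongest regions of replicate 1 were mitochondrial.

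Sites in mitochondrial DNA shared by both replicates may explain these peaks, but 0 of the 18 had a region of replicate 2 within 100 bp. That count decides nothing while replicate 2 lists no mitochondrial region at all, where its 30000 regions would give 4.13 by length alone (Poisson probability of 0, 0.0161). Mitochondrial reads removed or nearly lacking in replicate 2 before peak calling could give the same 0, and shared sites would then be hidden. Signal spread over the mitochondrial genome of replicate 1 is a further candidate explanation, and its regions covered 42.9% of that genome, between the limits set for single sites (20%) and for spread signal (50%). At the rpl-3 peak the signal was 130 in the joint list, 65.2 in replicate 1 and 65.0 in replicate 2. The highest mitochondrial signal was 739 in the joint list, but no region of replicate 1 exceeded 364. If the signals of the replicates add up in the joint list, reads of replicate 2 contributed there, which would argue against reads nearly lacking in it. The score has no stated scale, so the 3 explanations are not told apart here. The reads of each replicate and the control were not analysed, and no biological explanation beyond shared sites was tested.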

How the results depend on the processing

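Nuclear or autosomal peaks only, weaker joint regions, joint-list genes and shuffled windows were chosen as alternatives after seeing the data. No IDR peak lay near nhr-12 or unc-119 at any distance run, where random positions gave a mean of at most 0.26. The match between replicates (29.3% to 45.1%) and the promoter share (35.6% to 69.2%) stayed above random placement under every alternative run. That promoter range leaves out the X peaks taken alone (24.1%, with a mean of 10.4% at random). The stronger part of the IDR set held 82 peaks. With it the number past the threshold was 2 chromosomes (4 in the main result), 1 gene list (of 3), 1 noncoding RNA class (of 3), 0 sequence patterns (of 7) and 1.78% of hexamers (of 10.5%, or 218), and this set has fewer peaks by construction. In it intergenic peaks (30.3%, 28.9% at random) and peaks near tRNA genes (0, 0.221 at random) changed direction without passing. Expected shares from regions in both lists gave 2 chromosomes. An upstream limit of 250 bp gave 1 gene list, and joint-list genes as background gave 1. Sequence patterns numbered 4 with windows of 50 bp each side, 4 with 200 bp and 3 against shuffled windows, where TTTCAG changed direction without passing (odds ratio 1.09). The hexamers past the threshold were 6.54% of all with 50 bp each side, 23.3% against promoters without a peak, 21.7% against weaker joint regions, 4.28% against shuffled windows and 6.88% with autosomal peaks only. Apart from the smaller peak set, the cause was not tested. Leaving out 1 replicate in turn gave 2 to 3 chromosomes, 3 to 4 feature classes, 2 to 5 gene lists, 4 to 5 sequence patterns and 5% to 10.5% of hexamers. The lower number of hexamers and chromosomes and the higher number of lists came without replicate 2. The ce10 lists were matched to random placements drawn with ce11 chromosome lengths. Among single named results, 49 values lost and 2 gained the threshold in the same direction, 3 changed direction and 145 did neither. No paired analysis was possible because there was 1 group, and read depth, which limits weak regions, was unknown.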

Other observations

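Chosen after the result was seen were the tests of the weaker X regions, of repeats, of shuffled windows, of X signal strength, of the core by position on X and of the densest stretch. Beyond the genes named by rule, the 102 genes included 3 members of the DREAM complex, which represses transcription: lin-9 (signal 45.4), lin-53 (39.7, a peak shared with nra-2) and lin-54 (45.9, a peak shared with rpl-12). Also among them were tba-2 (62.9), for an alpha-tubulin, and the divergent pair F44E5.4 and F44E5.5 (58.9, a single peak). These genes were picked after their values were seen and form no tested group.

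The densest 500 kb of nuclear peaks was on the right arm of chromosome I, where 10 IDR peaks had midpoints between 13297749 and 13756569, 6 of them in promoter windows. They included the peaks at rpr-1 and ints-4. Random placements within chromosomes gave a densest window of 5.28 peaks on average and of 10 at most (n = 146 peaks, 10000 draws, p = 0.0002). The joint list held 59 regions in this window against a chromosome mean of 21.9, the replicate 1 list 232 against 142 and the replicate 2 list 243 against 155. Of each replicate's 164 strongest regions, 8 of replicate 1 and 10 of replicate 2 lay there.

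The X peaks were stronger than the autosomal ones, with a median joint signal of 64 against 46.8 (permutation p = 4e-05), and X held 19 of the 50 strongest nuclear peaks (38%) against 17.7% by length. A background raised over all of X was argued against by the weaker joint regions, of which 18.5% were on X (95% interval 17.2 to 19.8), and repeats by a median soft-masked share of 13.9% in the X windows, below the 26.9% of random X windows. A candidate explanation is that some X peaks lie at recruitment sites of the dosage compensation complex, whose recruitment motif has the core GCGCAGGG: that core was in 12 of 29 X peaks and 1 of 117 autosomal ones (Fisher exact odds ratio 77.9, 95% interval 10.4 to 3528, p = 4.84e-09). It was in 4 of 674 weaker X regions, in 12 of 22 X peaks outside promoter windows and in 0 of the 7 inside (Fisher exact adjusted p = 0.023), but not in the strongest X peak (K02D3.5) or that near ZK899.10, and the full motif TCGCGCAGGGAG was in 2 of the 29 X peaks and 0 of the 117 autosomal ones. Whether NHR-12 itself or open chromatin at such sites gives the signal stays open, since no control sample or second factor was analysed here.

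For the promoter peaks, direct contact of the receptor with AGGTCA sites may contribute, but the odds ratio of 2.06 had an interval from 0.748 to 5.65, which leaves it open. For RNA polymerase III genes with an internal B box, the odds ratio of 0.277 in the joint call had an upper limit of 0.736, under the 1.5 set beforehand. Replicate 1 alone (0.854, upper limit 1.93) did not meet that limit. The pattern was in 11.4% of flanks, so its share among all windows cannot exclude such genes at a few peaks. By position, tRNA genes had 2 peaks against 0.425 in random placements (n = 146, adjusted p = 0.0987), which leaves this open. Base composition alone was argued against for the EOR-1-like pattern (odds ratio 142 against shuffled windows, 95% interval 21 to 6064) and for the GAGA box and E2F pattern, of which the lower odds ratio was 2.07 (95% interval 1.32 to 3.16). For the less frequent GATA, HSF and TTTCAG patterns taken as a set, base composition stays open. Their odds ratios against shuffled windows were 0.842 or more, with intervals that include 1. Those of TTTCAG (0.662 to 1.73) and HSF (0.435 to 1.65) exclude the values against flanks (0.37 and 0.42), as base composition would give. That of GATA (0.546 to 1.27) includes its value against flanks (0.552). Base composition stays open for the B box too, whose odds ratio of 0.357 (95% interval 0.112 to 0.876, Fisher exact adjusted p = 0.089) remained near that against flanks.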
